A study of Gallus gallus with 6 samples.

How the data were processed

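RNA was extracted from chicken ES cells at passage 10 and from cells of freshly laid embryos with a column kit, and libraries were made with a BGISEQ-500 protocol, per the labels' protocols. The cells had been grown at 38 °C with 2.5 µM IWR-1, 2 µM Gö6983 and 2 µM SB431542, per the labels. Their medium also held 10 ng/ml chicken LIF and 10 ng/ml ovotransferrin. The egg storage temperature in the labels is 16 °C for both groups. FastQC, STAR, RSEM and DESeq2 are named in the submitters' processing notes, without versions. The genome builds and annotations are not given in the sources used here.

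The authors deposited 1 table per library with expected counts per gene (estimated read counts that need not be whole), TPM values and the mean length and effective length of each gene's transcripts, per the file headers, which are those of RSEM. The deposited expected counts are not normalized, and 91% to 93.9% of the listed values, with those of 0 included, were whole numbers within 1e-09. Among values above 0 the share was 86.3% to 91.5%. The deposited TPM values are scaled to the same sum over all IDs of a file, per the file headers and their sums. The tables of the cells and of the embryos list different gene and transcript IDs, with 38118 transcripts in the cell files, 39288 in the embryo files and 21312 in both. A read can only be counted for a feature that the model set holds, and a longer model collects more reads, so the counts of an ID with unlike models are not directly comparable between the groups. Comparisons used the 15900 shared IDs. They were sorted into 2775 identical models (1 transcript with the same ID, and the same length within 0.005 bases), 4474 with 1 transcript of the same ID but another length, 1128 with the same list of several transcripts, and 7523 with other transcripts. Whether identical models also share their sequence is not recorded in the files.

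Samples were grouped by their titles. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with default settings, TMM factors, glmQLFit and glmQLFTest), cells against embryos, with all 6 libraries and no block. IDs with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and counts are also given for a log2 fold change of at least 1 and at least 4 in size. Standard errors were taken from the quasi-F statistic. The samples of both groups carry the numbers 1 to 3, and nothing in the labels says that these pair the samples. The correlations of same-numbered libraries' deviations from their group means were 0.018, 0.009 and -0.037, so the numbers were taken not to pair the samples. With 3 libraries per group this check cannot exclude a pairing.

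On counts simulated from these libraries over 11614 IDs, the test recovered 47 of 50 IDs changed 2-fold, 48 of 50 changed 4-fold, 31 of 50 changed 1.5-fold and 22 of 50 changed 1.25-fold, and called 16 of 11242 unchanged IDs. The simulation gave both groups the same spread, while the real spread was larger in the embryos, so these rates may not hold for the real libraries. It also changed few of the IDs, while 85.1% were called in the real libraries. The same adjusted p was therefore a stricter threshold in the simulation, and the recovery of small changes may be understated. At the depth of the libraries, 3 counts correspond to 0.182 to 0.241 CPM of the shared IDs. Intervals and floors on counts cover counting error only, since no molecular identifiers are given.

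Before the data were examined, 30 gene lists and a rule for named genes were fixed: a set of developmental genes, the 8 largest changes and the 6 most abundant changed genes in each direction among those with a symbol, and examples from each list. The files hold IDs of Ensembl type without names, and 0 of them occur in the RefSeq gene table (assembly GRCg7b) used for names. The lists and the parts of the rule that need symbols were therefore not run. In their place, and chosen after the gene models were seen, 2 IDs per direction are printed: among called identical models, the one with the largest fold change with a mean CPM of at least 10 in the higher group and groups that do not overlap, and the one with the highest mean CPM among those changed at least 2-fold. No positions in the genome are given, because the files hold none.

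The share of counts in the most abundant IDs was taken over all IDs of a library's file and compared with a two-sided exact permutation test. Alternatives tried were other scaling factors (DESeq2 size factors, upper quartile, library size alone), DESeq2 1.42.0, limma 3.58.1 (voom, voom with a weight per group, and limma-trend on log2(TPM + 1)), no filter and a filter of 1 CPM, effective length as an offset, the sample number as a block, an adjusted p under 0.01, each library left out, subsets of gene models, and counts thinned to the 12456924 of the smallest library. Figures were drawn with matplotlib 3.10.9. The IDs listed in the files of only one group were left out of the comparison.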

Results

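Gene expression was measured by RNA sequencing in chicken embryonic stem (ES) cells at passage 10 and in primary cells of freshly laid chicken embryos, with 3 libraries in each group. The embryos were at stage X of the Eyal-Giladi and Kochav series, when the chick is a flat blastoderm on the yolk that has not yet formed a primitive streak. The ES cells were derived from embryos of this stage and grown on irradiated mouse embryonic fibroblasts. Their medium held ovotransferrin and chicken LIF, a cytokine that acts through STAT3. It also held IWR-1, an inhibitor of tankyrase that lowers WNT signalling, and Gö6983, an inhibitor of protein kinase C. A further inhibitor, SB431542, acts on the activin and NODAL type I receptors. The design asks how the expression profile of the expanded cells compares with that of the embryo cells they came from. The labels do not say whether the 3 libraries of a group came from separate lines, cultures or embryos, so the p-values measure the spread between these libraries, which may be technical.

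The cell libraries held 13403975, 13007413 and 13208360 expected counts and the embryo libraries 16068898, 17082488 and 16118546. The files of the 2 groups were not made with the same gene models. The cell files listed 24881 gene IDs and the embryo files 24356, of which 15900 were in both. The shared IDs held 95.8% of the counts of each cell library and 96.4% to 96.6% of those of the embryo libraries. Of the shared IDs, 8377 had the same list of transcript IDs in both groups, and 2775 had a single transcript of the same ID and the same length. These 2775 are called identical models here, since transcript ID and length are alike in both groups' files. The gene model set and the group could not be told apart for the other 13125 shared IDs. The files give no gene names or coordinates, and none of the IDs occurs in the gene table used for names, so the results are given for groups of IDs and for 4 IDs chosen by rule.

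ES cells and embryos differed in most of the expressed transcriptome. Of 11614 IDs tested, 9883 (85.1%) changed, with 4870 higher and 5013 lower in the cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median size of a called change was 1.06 on the log2 scale, and 5144 IDs changed at least 2-fold, with 2425 higher and 2719 lower. Groups did not overlap for 86.2% of the tested IDs, against 10% expected by chance for 3 libraries against 3. When effective length was used as an offset, to take out the difference in gene model length, 9754 IDs changed, and 8552 of the 9883 were called again in the same direction. For 650 of the 9883 the sign of the fold change turned under the offset. The offset also moved the common scale, as the median log2 fold change of the identical models went from -0.18 to -0.36. Kept calls and turned signs therefore mix this shift with the length correction. The direction of a single ID with unlike models is uncertain.

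Most of the identical models also changed, and the counts of these IDs carry no difference in gene model length, although their scaling factors are shared with the other IDs. Of 1108 such IDs tested, 932 (84.1%) changed, with 403 higher and 529 lower in the cells, and 505 changed at least 2-fold, 199 higher and 306 lower. The share called was 85.2% among the other IDs, and the odds ratio of 1.09 did not pass Fisher's exact test (two-sided p = 0.33, adjusted p = 0.494 over 3 tests). Fitted on their own, the identical models gave 890 calls of 1090 tested, 433 higher and 457 lower. That fit sets its scaling factors from these IDs alone. The median log2 fold change of the identical models was -0.18 in the fit of all IDs, -0.36 with the length offset and -0.04 fitted on their own, so the split between higher and lower depends on the scaling. Called changes among the identical models had a median size of 1.14 on the log2 scale.

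**Figure D1:**
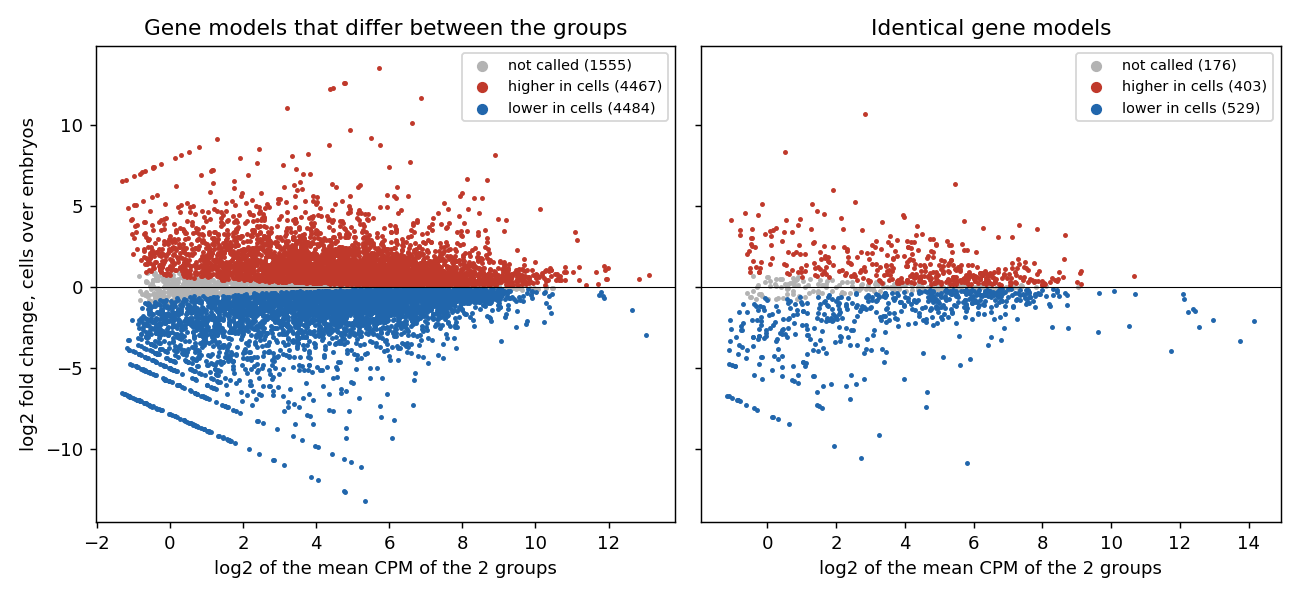
Log2 fold change of cells over embryos (y axis) against the log2 of the mean CPM (library-scaled counts) of both groups (x axis), 1 point per tested ID, for IDs whose gene models differ between the groups' files (left) and for identical models (right). Red points are higher and blue points lower in the cells at an adjusted p under 0.05, and the slanting rows of points at the edges are IDs with 0 or few counts in 1 group, whose fitted fold change depends on the prior count; both panels hold calls in both directions, 403 higher and 529 lower among the identical models.

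More of the large changes were lower than higher in the cells. At least 16-fold changes were found for 742 IDs, of which 512 (69%) were lower and 230 higher in the cells. Among the identical models the corresponding numbers were 69 lower and 19 higher. These changes made up 7.94% of the tested identical models and 6.23% of the other tested IDs, a difference that did not pass after adjustment (odds ratio 0.769, Fisher's exact test, two-sided p = 0.0328, adjusted p = 0.0983 over 3 tests). Many of the large changes were IDs with 3 or fewer counts summed over the lower group, whose fitted folds are not precise. They made up 282 of the 512 lower and 56 of the 230 higher IDs. With those set aside, 230 IDs were lower and 174 higher, and 27 and 13 among the identical models. On the log2(TPM + 1) scale, which compresses low values, 61 IDs were lower and 55 higher by 16-fold, so the numbers lay closer on that scale. Complete switches, under a strict rule of exactly 0 counts in 1 group, were rare among the tested IDs. IDs listed for only 1 group could not enter this count. Only 17 tested IDs had a mean CPM of 10 or more in one group and 0 counts in all libraries of the other, 7 present in the cells and 10 in the embryos. They made up 0.181% of the tested identical models and 0.143% of the other tested IDs (odds ratio 0.791, 95% interval 0.184 to 7.13, Fisher's exact test, two-sided p = 0.674).

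The IDs named here were the largest and the most abundant change in each direction among the identical models. ENSGALG00000043909, a 741-base transcript, was present in the cells at 14.3 ± 1.88 CPM (SD, n = 3) and had 0 counts in all embryo libraries. Its level was 224-fold higher in the cells with the embryos set at the limit of 3 counts over the group that a count of 0 allows. The lower limit of the 95% counting interval was 181-fold. ENSGALG00000016665, with a 2611-base transcript, was the most abundant identical model with a rise of 2-fold or more. It stood at 725 ± 26.7 CPM in the cells and 78.8 ± 0.339 CPM in the embryos (SD, n = 3), a log2 fold change of 3.20 ± 0.05 (SE, edgeR adjusted p = 1.65e-13). ENSGALG00000017052, with a 1500-base transcript, had 112 ± 26 CPM in the embryos (SD, n = 3) and 2 counts over the 3 cell libraries. The ratio was 2130 with a 95% counting interval of 591 to 17600 (edgeR adjusted p = 3.32e-11). ENSGALG00000032142, with a 1548-base transcript, had the highest mean CPM of the tested IDs in the embryos, 29500 ± 7460, and stood at 7080 ± 44.1 CPM in the cells (SD, n = 3). Its log2 fold change was -2.06 ± 0.13 (SE, edgeR adjusted p = 1.49e-08).

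A few very abundant IDs held a larger share of the counts in the embryo libraries than in the cell libraries. The 10 most abundant IDs of each library held 12.5% ± 2.3 of the counts in embryos and 5.82% ± 0.076 in cells (SD, n = 3), a ratio of 2.15. The 50 most abundant IDs held 22.1% ± 2.1 in embryos and 15.4% ± 0.14 in cells. Among the 20 IDs with the highest mean CPM over all 6 libraries, 9 had identical models, and together they held 10.6% ± 2.2 of embryo counts and 2.93% ± 0.036 of cell counts. Over the shared IDs the ratio of the top-10 shares was 2.14, and it was 1.39 without 8 of these 20 IDs, chosen by transcript length and all lower in the cells (8.67% ± 0.79 in embryos and 6.22% ± 0.081 in cells, SD, n = 3). All 3 embryo libraries lay above all 3 cell libraries in each of these measures. The exact permutation test gave a two-sided p = 0.1 for each, the smallest that 3 against 3 allows, and 0.1 after adjustment over 8 such shares. The third embryo library was the highest, with 15.2% in its 10 most abundant IDs against 11.1% and 11.2% in the other embryo libraries.

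**Figure D2:**
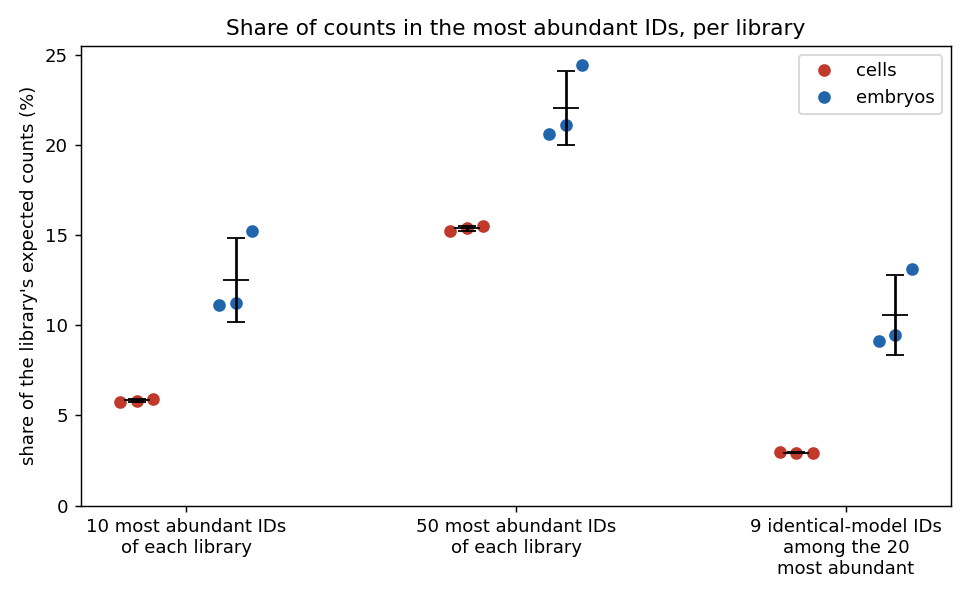
Share of each library's expected counts (y axis, %) held by its own 10 and 50 most abundant IDs and by the 9 identical-model IDs among the 20 most abundant overall. Points are libraries, and bars are the mean and SD of 3; the embryo libraries (blue) lie above the cell libraries (red) throughout, at 11.1% to 15.2% against 5.76% to 5.91% for the 10 most abundant IDs.

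Cell libraries were closer to one another than embryo libraries were, a description for which no test was run. The mean Spearman correlation across genes was 0.9981 between cell libraries, 0.995 between embryo libraries and 0.8388 between the groups, where genes are not independent replicates. Without the low-count filter the values within cells and within embryos lay closer, at 0.9951 and 0.9944. The biological coefficient of variation was 2.57% in the cells and 9.0% in the embryos, a ratio of 3.51, and 6.45% in the pooled fit. Against Poisson sampling, the chi-square per degree of freedom was 1.48, 2.23 and 1.51 for the pairs of cell libraries, and 11, 18.1 and 19.6 for the pairs of embryo libraries. Each pair differed by more than Poisson noise, so none was treated as a single library deposited in 2 files. Expected counts are estimates and need not follow Poisson noise, and the cell pairs lay closer to it than the embryo pairs. The check therefore does not exclude 1 RNA sample sequenced again, and does not show that the libraries came from separate cultures or embryos.

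The fold changes also followed the difference between the gene models. The embryo files gave the longer model for 7469 of the tested IDs and the cell files for 2871. Where the embryo model was at least 2-fold longer (773 IDs), the median log2 fold change was -1.39, and where the cell model was more than 2-fold longer (185 IDs), it was 1.70. With effective length as an offset these medians were 0.08 and -0.20. The Spearman correlation of the fold change with the log2 length ratio was 0.238 across the 11614 tested genes and -0.065 with the offset. Genes are not independent replicates in this correlation.

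**Figure D3:**
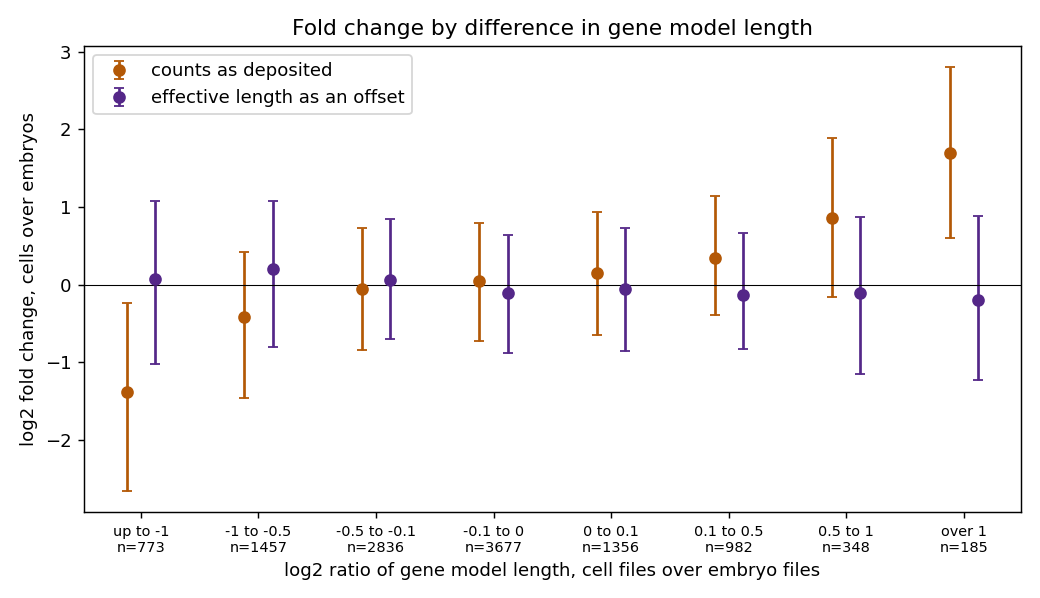
Median log2 fold change of cells over embryos (y axis; bars span the quartiles of the IDs) by the log2 ratio of gene model length in the cell files over the embryo files (x axis), with the number of IDs under each bin. With the counts as deposited (orange) the median runs from -1.39 to 1.70 over the bins, and with effective length as an offset (purple) it stays between -0.20 and 0.21.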

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

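The tests of gene models and model length reported here were chosen only after the result was seen; the splits of the samples were planned. IDs outside the comparison held signal. Of 8981 IDs listed only in the cell files, 808 had a TPM of 10 or more in all 3 cell libraries, and together the 8981 held 4.23% ± 0.0216 of cell counts (SD, n = 3). Of 8456 IDs listed only in the embryo files, 525 had a TPM of 10 or more in all 3 embryo libraries, and together they held 3.51% ± 0.126 of embryo counts (SD, n = 3). None of these IDs can be compared between the groups.

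The number of IDs called was 9883 for the real grouping. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many, the real one, and the highest of the other 9 called 0 with edgeR and 0 with limma-voom, with at most 5 IDs at an unadjusted p under 0.05. A share under 0.05 cannot be reached with 10 splits. Each of the other 9 splits mixes cells with embryos, so the difference between the groups enters its spread and few calls could arise. The splits therefore say nothing for or against chance. The different gene models of the 2 groups' files are argued against as the whole explanation, because 81.7% of the IDs tested were called when only identical models were fitted. What stays open, as untested, is the biological difference that the design names, cells expanded in culture against embryo cells. Any other difference between the groups in handling or processing cannot be told apart from it. The mouse fibroblasts on which the ES cells were grown are such a difference. Whether RNA of these fibroblasts entered the counts of the cell libraries was not tested.

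The second pattern is the relation of fold change to model length, for which read counts that scale with the length of the gene model are a candidate explanation. Over the 3129 IDs with 1 transcript of the same ID but another length, the Spearman correlation across genes was 0.35 before and 0.019 with effective length as an offset. Over all 11614 tested IDs it was 0.238 before and -0.065 with the offset. The medians at the most unlike lengths changed sign, from -1.39 to 0.08 and from 1.70 to -0.20. The correlations left with the offset, 0.019 and -0.065, differ in sign. They do not show whether the offset corrected too much or too little. Changes of single IDs with unlike models may thus be partly or wholly made by the models, in either direction. No biological explanation was tested for this pattern, since the design gives none.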

How the results depend on the processing

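The identical-model, transcript-list, weighted, thinned and length-match settings, and those for the shares and the coefficient of variation, were added after seeing the data. The gene lists were not run, because the IDs have no names, and mitochondrial genes could be left out only by length. Calls numbered 9547 to 10706 under the other scalings, tests, filters, the length offset and the thinning, 9172 at an adjusted p under 0.01, and 9633 to 9959 with each library left out. The numbers were taken not to pair the samples, and with the replicate block 9823 IDs were called. The count fell with fewer IDs tested: to 890 for identical models and 4356 for IDs with the same transcript list, and for at least 2-fold changes from 5144 to 492 and 2450. Of the main calls tested there, 860 of 898 and 4224 of 4354 kept their direction and call. At least 16-fold changes went from 742 to 1114 without a filter, 116 on log2(TPM + 1), 72 for identical models and 404 for the same transcript list. Lower IDs made up 67% to 73.2% of them, but 52.6% on log2(TPM + 1). Sign changes among the 9883 calls arose with the length offset (650) and on log2(TPM + 1) (662), both of which correct for length. The offset also moved the common scale. Sign changes were 0 in the other settings. The 4 printed IDs kept direction and call in all 84 values from these alternatives, with adjusted p up to 2.42e-06. The log2 fold changes of ENSGALG00000043909 and ENSGALG00000017052, both near 0 counts in 1 group, shrank to 5.02 and -6.78 on log2(TPM + 1). The mean correlation within cells was 0.9975 on log2(TPM + 1), 0.9951 without a filter, 0.995 as Pearson's r, 0.997 for identical models and 0.9979 to 0.9983 leaving out libraries. Within embryos it was 0.9943 on log2(TPM + 1), 0.9944 without a filter, 0.9926 as Pearson's r, 0.9928 for identical models and 0.9937 to 0.9961 leaving out libraries. Between groups it was 0.8911 without a filter, 0.7969 as Pearson's r and 0.8531 for identical models. The embryo-to-cell ratio of the top-10 share was 2.98 in TPM, 1.39 over shared IDs without the length-matched ones (2.14 with them), 1.79 within identical models and 1.44 for the top 50. The cause of these moves was not tested. Thinning to the smallest library gave 9728 calls. At this depth and number of libraries, 31 of 50 simulated 1.5-fold changes were recovered. In that simulation both groups had the same spread and few IDs were changed, so the rate may not hold for the real libraries. The ratio of the coefficients of variation was 2.68 to 4.42 with each library left out.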

Other observations

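The tests in this part were chosen after the result was seen. Several of the very abundant IDs that were lower in the cells share a physical trait. Of the 20 IDs with the highest mean CPM, 8 have a single transcript whose length equals that of 1 of the 15 mitochondrial protein and ribosomal RNA genes in the RefSeq table. For 1 of the 8 the match holds in the embryo files only, where the length is 1039 bases against 1041 in the cell files. ENSGALG00000032142, the ID with the highest mean CPM in the embryos, has no match under this rule of equal length. The lengths of 1039 and 1041 bases show that the model of 1 ID can differ between sets. A missing match therefore does not show that ENSGALG00000032142 is not mitochondrial. All 8 were lower in the cells (edgeR adjusted p at most 5.5e-05), with log2 fold changes from -3.30 to -0.72. Together they held 8.68% ± 1.8 of embryo counts and 2.06% ± 0.026 of cell counts (SD, n = 3), a ratio of 4.2.

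The hypothesis is that these IDs are mitochondrially encoded genes that add to the larger share of the most abundant IDs in embryos. Among 10000 random draws of 20 tested IDs, the mean number of length matches was 0.0568 and the highest 2, against 8 observed (permutation p = 1e-04, the smallest these draws can give). The draws were not matched for abundance. With the 8 IDs left out, the embryo-to-cell ratio of the top-10 share over the shared IDs was 1.39, against 2.14 with them. ENSGALG00000032142 was not left out, with a mean of 29500 CPM in the embryos and 7080 CPM in the cells. As a share of counts, that difference covers most of the gap between the top-10 shares without the 8 IDs, 8.67% in embryos and 6.22% in cells. The ratio of 1.39 thus rests largely on ENSGALG00000032142, although the shares were not computed without it. All 8 were higher in the embryos, so a lower ratio was to be expected from their choice, and leaving out other abundant IDs was not tried. The 9 identical-model IDs among the 20 most abundant had a ratio of 3.61 with no overlap of the groups. Of the 8 length matches, 7 are among these 9, and ranking by the mean over all 6 libraries favours IDs that are high in embryos. The ratio of 3.61 is therefore not independent of the pattern. With the 10 most abundant identical models taken in each library, as a share of the counts of identical models, the ratio was 1.79 (65.5% ± 4.6 in embryos and 36.6% ± 0.04 in cells, SD, n = 3), also with no overlap. That ratio argues against the different gene models as the whole explanation. It stays open whether a higher mitochondrial RNA content of embryo cells may be the source, as this was not tested, and a length match does not name an ID.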
